A study of Arabidopsis thaliana with 12 samples.

How the data were processed

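Total RNA of wild-type Arabidopsis thaliana plants of the Landsberg ecotype was measured on an expression array in 12 columns of values. Per the labels, 6 columns came from plants treated with 50 µM paraquat and kept for 12 h in darkness, here called dark. The other 6 came from paraquat-treated plants sampled 30 min after return to light at the end of a 12 h dark period, here called light. Paraquat is a herbicide that takes electrons from photosystem I and passes them to oxygen. No untreated plants are among these columns, so the comparison concerns light against dark in the presence of paraquat, and paraquat itself cannot be separated from it. Time of sampling may also differ with light, by the 30 min in the labels, and cannot be told apart from it.

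The authors deposited 1 table of linear intensity values for 3439 probes, and the background treatment, scaling and other steps that made it are not given in the sources used here. The deposited intensity values held no negative number, between 129 and 148 exact zeros per column, and a shared ceiling of 100, which 11 of the 12 columns reached. Column totals ranged from 3466 to 3664 and column medians from 0.559 to 0.635. An exact zero is described only as listed at 0, since what it stands for is not given in the sources used here. The number of arrays limits the precision, and whether a background was subtracted stays unknown.

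Probes were named from the platform annotation, which can be old. Of the 3439 probes, 692 carried 1 gene name, 870 carried several and 1877 carried none. Only probes with 1 gene name were named, and 690 of these 692 were matched to a locus of the RefSeq table for assembly TAIR10.1, which was used for names only.

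The design, the tests, the alternatives and 24 gene lists were fixed before the data were examined. Columns were quantile-normalised with exact zeros kept at 0, and the values were transformed as log2(value + 2.53e-05), the offset being the lowest positive value of the table. Fold changes are therefore on this normalised log2 scale, whereas means ± SD are deposited intensities, so a ratio of the means can differ from the fold. The 30 probes at 0 in every column were left out, and 3409 probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Single summaries of the columns were compared with two-sided exact permutation tests, whose smallest possible p was 0.00216 for 6 against 6. Gene lists with at least 3 measured members were tested with camera (preset correlation 0.01, or an estimated correlation as an alternative) and fry. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

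The named genes follow a rule. Among probes past the threshold with 1 gene name and a mean intensity above the lower quartile of all probes (0.330), the 12 with the largest positive and the 12 with the largest negative log2 difference were taken. For each list, up to 4 measured members with the smallest p were added. A further 5 lists were drawn up from gene names after the data had been seen and are reported only with the additional observations.

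Nothing in the labels says that the columns of a group came from separate plants or cultures, so p-values measure the spread between these columns, which may be technical. The replicate numbers of the labels run from 1 to 6 in each group. Deviations from the group mean were correlated between same-numbered columns of opposite groups, over the 2554 probes above the lower quartile and without zeros. The correlation lay between 0.66 and 0.786 for the 6 numbers, with a mean of 0.713, and each of the 12 columns was best matched by its own number. By this check on the values the numbers pair the columns, and the fit with the replicate number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times. Columns of consecutive numbers in a group (1 with 2, 3 with 4, 5 with 6) also deviated together, with a mean correlation of 0.30, against -0.318 for other numbers of the group. The labels do not say that consecutive numbers are repeats and no columns held identical values, so each column was kept as a replicate, and averaged columns were an alternative. Repeated measurements of 1 sample need not hold identical values, so this does not show that consecutive numbers are separate samples. Throughout, n = 6 counts columns and may overstate the number of samples.

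The procedure was tested on simulated data for 3409 probes in 5 simulations, each with 200 changed probes. The fit without the block recovered 46.2% of changes of log2 0.5 and 87.0% of changes of log2 1, and 0.6% of its calls were unchanged probes. With the replicate block these values were 68.2%, 96.4% and 3.8%. The simulation drew the part shared by a number independently for each number, without the tie between consecutive numbers. These rates therefore apply only if consecutive numbers are separate samples. Of 100 simulated lists of 6 genes shifted by log2 0.5, 100 had an unadjusted camera p under 0.05, against 4 of 100 unshifted lists. The shifted genes were drawn at random from probes whose mean log2 value lay above the lower quartile. The measured plastid ribosomal list holds dimmer genes, with an estimated correlation of 0.18, so this share need not hold for it. Alternatives covered the scaling, the offset, a filter on dim probes, the block, averaged columns, moderation, array weights, an exact permutation test per probe, a fold limit and each column left out. Settings that averaged and blocked, left out a set of numbers, centred runs of probe numbers or left out probes with zeros were added after the data had been seen. The replicate block together with consecutive numbers as a random block was added then too.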

Results

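The data comprised 12 columns of deposited array intensities from paraquat-treated wild-type Arabidopsis plants, 6 from plants kept for 12 h in darkness and 6 from plants sampled 30 min after return to light. The comparison asked which transcripts differed between light and dark in the presence of the herbicide. Column totals of intensity ranged from 3466 to 3664.

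After return to light, 89 of the 3409 probes tested were higher and 108 were lower than in darkness (limma, adjusted p under 0.05, n = 6 per group). With the replicate number as a block, 448 probes passed, 228 higher and 220 lower, 179 of the 197 among them. The changes were small, with a median absolute log2 difference of 0.46 among the 197 called probes, or 1.37-fold, and 2 probes differed by log2 1 or more. Of the called probes, 39 named 1 gene, of which 17 rose and 22 fell. AT4G25290, annotated as a DNA photolyase, rose from an intensity of 1.27 ± 0.0597 to 2.25 ± 0.346 (SD, n = 6; log2 0.82, limma adjusted p = 0.00197). The transcript of AT5G58330, the NADP-dependent malate dehydrogenase of the chloroplast that exports reducing power as malate, fell from 2.66 ± 0.186 to 1.79 ± 0.165 (SD, n = 6; log2 -0.60, limma adjusted p = 0.00345).

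Among the other genes that rose, CCL, a clock-regulated transcript, had an intensity of 9.56 ± 1.53 in dark and 14.1 ± 1.84 in light (SD, n = 6; log2 0.45, limma adjusted p = 0.0134). AT2G03390, which encodes a protein with a uvrB/uvrC motif, rose by log2 0.48, and chr31, a chromatin remodelling factor, rose by log2 0.43. AT4G39690, which encodes the mitochondrial membrane-organising protein MIC60, rose by log2 0.37. AT4G33480, AT4G16410, AT3G04650, AT2G46300, AT1G50770, AT4G13220 and AT4G27510 rose by between log2 0.39 and 0.61. With the replicate number as a block, AT4G33480 and AT4G27510 no longer passed the threshold (limma adjusted p = 0.0552 and 0.0665). With the values as deposited, both missed it as well (0.0548 and 0.0741), as did AT3G04650 and AT4G39690 (limma adjusted p = 0.0829 and 0.0511).

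Among the genes that fell, Z-ISO, the zeta-carotene isomerase of carotenoid synthesis, went from 1.01 ± 0.109 to 0.677 ± 0.0922 (SD, n = 6; log2 -0.53, limma adjusted p = 0.00862). AT5G47030, the delta subunit of the mitochondrial ATP synthase, fell with a log2 difference of -0.47. AT5G48130, of the NPH3 family, and AT3G18870, of the mTERF family of organelle gene regulators, fell with log2 differences of -0.58 and -0.45. AT4G35660 had intensities of 7.01 ± 1.86 in dark and 4.76 ± 1.41 in light (SD, n = 6; log2 -0.77, limma adjusted p = 0.0378), but its call was lost as deposited (log2 -0.57, limma adjusted p = 0.159) and with columns centred on the median (-0.52, 0.165) or interquartile mean (-0.52, 0.166). AT5G47030 also missed the threshold under these scalings (limma adjusted p = 0.0706, 0.0532 and 0.0568). AT2G29180, AT1G63610, AT3G52070, AT1G03660, AT3G52550 and AT1G35210 fell with log2 differences between -0.67 and -0.51, AT1G63610 missing the threshold as deposited (limma adjusted p = 0.0517). Each of the 24 named genes past the threshold had the same direction in 6 of 6 same-numbered comparisons of light with dark, as did 187 of all 197 calls. The calls were made on these same columns, so this agreement is not independent support. With consecutive numbers as a random block, 8 of the 24 passed: AT4G25290, AT2G46300, CCL, AT1G50770, chr31, AT5G58330, AT3G52070 and Z-ISO, and the other 16 had limma adjusted p between 0.0714 and 0.218. Centring within runs of 96 probe numbers ended 10 calls, with limma adjusted p between 0.0625 and 0.305: AT4G33480, AT4G16410, AT2G03390, AT4G13220, AT4G27510, AT4G39690, AT1G63610, AT5G48130, AT3G52550 and AT1G35210. Their log2 differences after centring lay between 0.23 (AT4G39690) and 0.56 (AT4G33480) for those that rose. For those that fell they lay between -0.56 (AT1G63610) and -0.40 (AT3G52550).

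**Figure D1:**
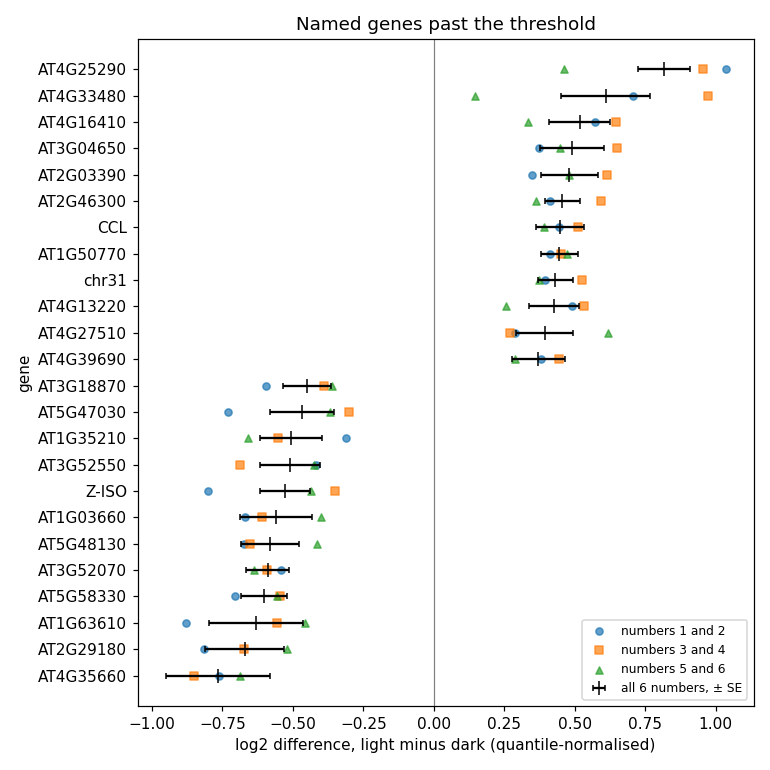
Log2 difference of light minus dark (horizontal axis, quantile-normalised intensities) for the 24 named genes past the threshold (vertical axis). Symbols are means of numbers 1 and 2, 3 and 4, and 5 and 6, and bars are the value over all 6 numbers ± SE. All symbols of a gene lie on 1 side of 0, from log2 1.04 for AT4G25290 to -0.88 for AT1G63610. The genes were chosen on these same columns.

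Probes without a gene name held 117 of the 197 calls. The smallest adjusted p of all probes belonged to probe_2758, which fell from 1.22 ± 0.120 to 0.695 ± 0.0314 (SD, n = 6; log2 -0.75, limma adjusted p = 0.00034). The next belonged to probe_2583, which rose from 0.412 ± 0.0346 to 0.669 ± 0.0455 (SD, n = 6; log2 0.73, limma adjusted p = 0.00134).

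Few genes of the 24 fixed lists were measured by a probe that names 1 gene: 20 of 429, and 15 lists had none. The photosystem II and antenna list had 4 measured members with a median log2 difference of 0.08 (0.16 with columns centred on the median, and -0.036, the opposite direction, without dark column 2), none past the threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 0.307, and adjusted p = 0.465 with an estimated correlation; fry adjusted p = 0.221). That member was PSBW, a small photosystem II subunit, at 17.7 ± 1.87 in dark and 23.9 ± 1.55 in light (SD, n = 6; log2 0.24, limma adjusted p = 0.0543, and 0.0409 with the replicate block). PSBW passed the threshold under each other scaling, with log2 differences of 0.44 as deposited, 0.48 with columns centred on the median and 0.48 on the interquartile mean (limma adjusted p = 0.0113, 0.0124 and 0.0121). LHB1B2, PSB27 and PSBY had log2 differences of 0.01, 0.14 and -0.002. As deposited these were 0.136, 0.083 and -0.041, and with columns centred on the median 0.184, 0.130 and 0.007, none past the threshold. The plastid ribosomal protein list had 6 measured members with a median of -0.06 (-0.246 without dark column 1), none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.307, and adjusted p = 0.465 with an estimated correlation; fry adjusted p = 0.283). The members AT4G01310, for RPL5, AT1G29070, for RPL34, and AT3G54210, for RPL17, had log2 differences of -0.27, -0.37 and -0.11. AT1G64510, for RPS6, had a difference of 0.16, and AT5G65220, for RPL29, was listed at 0 in 10 of 12 columns. By numbers 1 and 2, 3 and 4, and 5 and 6, RPL5 had 0.04, -0.27 and -0.57. RPL34 had -0.09, -0.15 and -0.86 in the same order.

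No measured member of the other 7 lists passed the threshold over all genes. AT3G52960, the chloroplast peroxiredoxin PRXIIE, had a log2 difference of -0.23 and was lower in light in 6 of 6 numbers (limma adjusted p = 0.122, and 0.024 with the replicate block). It did not pass when consecutive numbers were averaged and blocked, where 0 probes passed. NTRC, a plastid thioredoxin reductase, had a log2 difference of 0.30 (limma adjusted p = 0.188). The Calvin cycle genes SBPASE and PRK had differences of -0.13 and -0.06, and CHLM and AT1G74470 of chlorophyll synthesis had -0.09 and -0.02. PSAN of photosystem I, FATB of fatty acid synthesis, the plastid protease SPPA and the ferredoxin-thioredoxin reductase gene AT2G04700 had differences of 0.17, -0.09, -0.01 and 0.01. PSAN had 0.34 as deposited and 0.39 with columns centred on the median (limma adjusted p = 0.44 and 0.406).

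Of the called probes, 45.2% were higher in light (95% Wilson interval 38.4 to 52.2), and with the values as deposited this share was 34.6%, from 62 higher and 117 lower. With columns centred on the median it was 52.2%, from 109 higher and 100 lower, and on the interquartile mean 50.7%, from 107 higher and 104 lower, so the balance of directions turned with the scaling. The Wilson interval takes the probes as independent and does not measure the spread between samples. The median of the deposited columns did not differ between the groups beyond their spread (log2 -0.05, two-sided exact permutation p = 0.173, n = 6). The 5 brightest probes took 11.1% ± 0.434 of the column total in dark and 9.0% ± 0.433 in light (SD, n = 6; two-sided exact permutation p = 0.00216, the smallest possible for 6 against 6). These permutation tests take the columns as independent, which the correlations of same-numbered and of consecutive columns argue against. The share of the brightest probes includes values at the ceiling of 100, which 11 of the 12 columns reached.

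The number of calls depended on how the columns were treated as replicates. With consecutive numbers averaged to 3 columns per group, limma called 0 probes, with 335 at an unadjusted p under 0.05, and with consecutive numbers as a random block it called 42. Neither fit used the pairing by replicate number. In fits added after the data had been seen, the replicate block and the random block together gave 236, of which 126 were among the 197. Averaged and blocked columns gave 0, and 298 with a larger offset and without the dimmest probes, 145 of them among the 197.

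**Figure D2:**
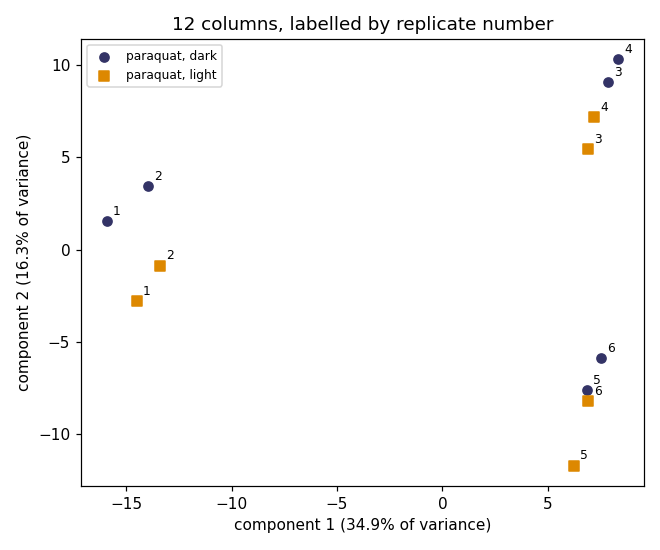
The 12 columns on the first principal components of the log2 intensities of 2554 probes, with circles for dark, squares for light and replicate numbers beside them. Component 1 (34.9% of the variance) parts numbers 1 and 2 from the rest, and component 2 (16.3%) parts numbers 3 and 4 from numbers 5 and 6.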

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

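The size ratios after centring, the tests of shared place on the array, of shared plant material and of repeated hybridisation, the bound for the whole effect of runs of probe numbers, and the splits by sets of consecutive numbers were chosen after the results had been seen.

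In 7 of 116 groups of 6 values, 1 column stood far from the other 5, where chance gives about 5.8. In dark, column 2 had an intensity of 0.880 for NTRC, against 0.524 to 0.653 in the other columns, and 0.502 for ATAB2, against 0.209 to 0.285. CRR21 was at 1.16 in dark column 5, against 1.32 to 1.42, and FATB at 0.0657 in dark column 1, against 0.148 to 0.190. In light, column 6 was low for AT3G52550, at 0.345 against 0.422 to 0.460, and for CRR41, at 0.858 against 0.948 to 0.996. LHB1B2 was at 14.8 in light column 5, against 10.4 to 12.0.

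The count of 197 probes was set against other splits of the 12 columns. Of 100 splits drawn from 462, 1 gave as many calls, the real one, and the highest other split, which parted 2 numbers, called 77. These free splits take the columns as independent, which the correlation of same-numbered columns argues against. Among the 32 splits that part every same-numbered pair, 1 gave as many, again the real one, so chance was excluded at the level of the 6 numbers, provided that consecutive numbers are separate samples. The other 31 exchange light and dark within 1 to 5 numbers, and limma called 0 probes in each, with 22 to 330 at an unadjusted p under 0.05. If consecutive numbers are taken as 1 sample, 4 splits remain, of which 1 gave as many and the highest other gave 0, and 4 are too few for a share under 0.05. For the lists, 31 of 100 splits shifted the photosystem II median as far as the real 0.08, with 0.14 as the highest other, and 63 of 100 shifted the plastid ribosomal median as far as 0.06, with 0.27 as the highest other, so chance was not excluded for either. Only free splits were used for the lists, so the pairing of same-numbered columns was not taken into account.

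All 197 calls were lost on averaging consecutive numbers. Averaging called at most 0 probes in each of the 14 other ways of pairing the 6 numbers too, so the loss was not particular to consecutive numbers. Because every pairing gave the lowest possible count, this comparison cannot tell fewer samples after averaging from a tie between consecutive numbers. With consecutive numbers as a random block, where no columns were averaged, limma called 42 probes, all among the 197. Allowing for a tie thus lowered the count without averaging, and fewer samples may add to the loss. Such a tie is present as well: differences of light minus dark correlated by 0.526 on average within consecutive numbers, above 0.46, the highest of the 14 other pairings, which is what consecutive numbers that repeat one hybridisation could give. A shared batch of plants could give the same value, and no biological explanation was tested. When averaged columns were also blocked, 0 probes passed, and with a larger offset and without the dimmest probes 298 did. The loss with averaged and blocked columns thus also depended on the offset or the dim probes, which were changed together, so the count stays open.

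Columns of 1 number deviated together across the groups, with a mean correlation of 0.713. A shared place on the array is a candidate explanation: the deviation shared by a number correlated by 0.274 between neighbouring probe numbers, against at most 0.06 in 1000 shuffles. Whether probe numbers follow the layout is not given in the sources used here. Plant material shared by a number cannot be told apart from it, because no label says what a number marks.

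Neighbouring probe numbers also moved together in light minus dark, with a correlation of 0.119 against at most 0.076 in 1000 shuffles. Centring each column within runs of 96 probe numbers left 106 of the 197 calls past the threshold (the bound for this count was set with the count known), and the 197 differences kept their direction and a median 0.956 of their size, which argues against a shift shared within runs as the whole source. The count of 106 lay below the 111 to 139 kept with 20 sets of shuffled runs, which met the bound stated beforehand for such a shift as a part of the source. The median ratio of the SE, 1.047 against 1.061 to 1.098, also lay outside the range of shuffled runs. The total called, 131 against 127 to 169, and the size ratio, 0.956 against 0.946 to 0.996, lay within it. No bound was stated beforehand for the total or for either ratio, and the values differ, so a part is left open. After centring, the neighbour correlation was 0.077, so an effect on a finer scale stays open, as does a response shared by genes with neighbouring numbers.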

How the results depend on the processing

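Settings with averaged and blocked columns, without a set of numbers, with centred runs or without probes with zeros were chosen after the data had been seen. So was the fit with the replicate block and a random block together. No call of the 197 changed direction in any setting. The count lay between 179 and 213 as deposited, with columns centred on the median or interquartile mean, with the larger offset, without the dimmest probes, with trend and robust moderation and without probes with zeros, and was 236 with array weights. It was 448 with the replicate block, 42 with consecutive numbers as a random block, and 236 with the replicate block and a random block together, which shared 126 of the 197. It was 2 with a fold of at least 2 required. Averaging consecutive numbers gave 0 (335 at an unadjusted p under 0.05), averaging with a block gave 0 (618), and averaging with a block, the larger offset and no dim probes gave 298, of which 145 were among the 197. The exact permutation test per probe gave 0 (691 at an unadjusted p under 0.05): its smallest adjusted p was 0.0505, with 146 probes at the smallest possible p of 0.00216, where 7.4 are given by chance. Without numbers 1 and 2 the count was 44, without 3 and 4 it was 0 (453), without 5 and 6 it was 87, and centring within runs of 96 gave 131, of which 106 were among the 197. Leaving out 1 column gave 103 to 168. The count moved by over 1.5 times without dark column 2 (121), 3 (126) or 4 (117), and without light column 1 (110), 2 (121), 3 (112), 4 (103) or 6 (115), with fewer samples in each. The share higher was 34.6% as deposited and 54.0% with averaging, block, larger offset and no dim probes. The correlation of same-numbered columns was 0.283 over all probes tested, which include those listed at 0. The replicate block ended the calls of AT4G33480 and AT4G27510, and of AT4G17260, AT5G35100 and AT1G01250, and brought PSBW and AT3G52960 past the threshold. It changed no other call of the genes named by the rule, and no list call. PSBW and AT3G52960 did not pass with averaged and blocked columns and the lowest positive value as offset, where 0 probes passed. Of the 24 calls named by the rule, 16 were lost with the random block, 24 with averaging, 7 as deposited, 2 with columns centred on the median or interquartile mean, 10 with centred runs and 4 to 11 on leaving out 1 column. The replicate block and a random block together lost 6 of these calls. Averaging with a block lost 24, and averaging with a block, the larger offset and no dim probes lost 1.

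Genes that changed sign were uncalled, and the cause was not tested. AT2G04700 was -0.004 as deposited, -0.017 with array weights, -0.054 without numbers 1 and 2, -0.008 without 5 and 6 and -0.019 with centred runs. PSBY was 0.007 and 0.006 with columns centred on the median and the interquartile mean, 0.069 without numbers 3 and 4 and 0.054 without 5 and 6. LHB1B2 was -0.004 with array weights, -0.009 without numbers 1 and 2, -0.001 without 5 and 6 and -0.007 with centred runs. Without numbers 3 and 4, SPPA was 0.068 and FATB 0.278. Without numbers 5 and 6, PRK was 0.017, CHLM 0.022, AT1G74470 0.012 and SPPA 0.004. With centred runs PRK was 0.042, CRR21 0.062 and SPPA 0.026. Leaving out 1 column gave -0.152 to 0.035 for PRK, -0.096 to 0.300 for PSB27, -0.041 to 0.049 for LHB1B2, -0.045 to 0.044 for PSBY and -0.173 to 0.002 for CHLM. It gave -0.104 to 0.050 for AT1G74470, -0.078 to 0.053 for SPPA, -0.293 to 0.173 for FATB and -0.062 to 0.061 for AT2G04700. The photosystem II list had a median of -0.036 without dark column 2 and up to 0.139 without dark column 6, and it was 0.157 and 0.156 with columns centred on the median and interquartile mean and 0.149 without numbers 5 and 6. The plastid ribosomal list had -0.246 without dark column 1 to -0.018 without dark column 6, and -0.178 without numbers 1 and 2. Background is not given, so signal over background could not be set.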

Other observations

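Lists drawn up from gene names, and the comparison of held-out numbers, were chosen after the data had been seen.

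Further named genes past the threshold lay outside the rule for named genes and were chosen after their values were seen. FZL, a dynamin-related protein of thylakoid membranes, rose by log2 0.36 (limma adjusted p = 0.0389), and AT5G17630, the xylulose 5-phosphate translocator of the plastid envelope, rose by log2 0.35 (limma adjusted p = 0.0282). AT4G17260, a lactate dehydrogenase, rose by log2 0.34 (limma adjusted p = 0.0428, and 0.0571 with the replicate block). AT5G35100, a cyclophilin-type isomerase, fell with a log2 difference of -0.44 (limma adjusted p = 0.0282, and 0.0616 with the replicate block). The transcription factor genes AT1G01250, of the ERF family, and AT2G37000, of the TCP family, fell with log2 differences of -0.43 and -0.34 (limma adjusted p = 0.0393 and 0.0401), the former at 0.0501 with the replicate block.

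None of the 5 added lists passed camera, where the smallest adjusted p was 0.458 and the smallest with an estimated correlation 0.513. By fry, which does not compare a list with other genes, 2 of the 5 passed: Calvin cycle and plastid redox enzymes (adjusted p = 0.0176) and endoglucanases (adjusted p = 0.0348), both at 0.0276 with the replicate block. The other lists had fry adjusted p of 0.145 for pigment synthesis, 0.329 for photosynthetic complexes and 0.831 for organelle factors. These lists were drawn up with the data at hand, and the lists that passed each hold a gene listed at 0 in some column, so their fry values are not independent evidence. Among the 9 members of the list called Calvin cycle and plastid redox enzymes, AT5G58330 fell and no other member passed over all genes. The name of this list is loose for its members GLDH and CCS. The median was -0.06 and the mean 0.07, apart in sign because CCS was listed at 0 in 3 columns. SRX, the sulfiredoxin gene, had a log2 difference of -0.24. Among 5 genes of pigment synthesis Z-ISO fell, and HEMA3, a glutamyl-tRNA reductase gene, had a log2 difference of 0.36, higher in light in 6 of 6 numbers (limma adjusted p = 0.0939). HEMA3 passed the threshold with centred runs (log2 0.47, limma adjusted p = 0.0337) and without dark column 1 (log2 0.43, limma adjusted p = 0.0437). No member passed among 11 genes of photosynthetic complexes and their assembly (median 0.14, mean -0.05), where CCB3 was listed at 0 in 6 columns and PIFI in 1. CRR41 and LPA19 of that list had log2 differences of -0.13 and 0.22. No member passed among 6 organelle RNA and DNA factors (median -0.01), in which OTP70, ATAB2, PAC and CRR21 had log2 differences of 0.30, -0.20, -0.19 and -0.05. The 4 endoglucanase genes of the GH9B family with a probe of their own had a median of 0.22, none past the threshold under the chosen settings. Of these, GH9B11, GH9B8 and GH9B16 had log2 differences of 0.22, 0.23 and 0.14, and GH9B12 was listed at 0 in dark column 1. GH9B12 passed the threshold with the larger offset (log2 0.71, limma adjusted p = 0.0496) and without dark column 1 (log2 0.88, limma adjusted p = 0.0284), while its value with the small offset rests on that zero and is not given.

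The direction of the strongest differences repeated in numbers that took no part in choosing them. The 100 probes with the smallest p over 4 of the numbers were chosen, and their direction was read in the other numbers. It was the same for 97 of 100 in numbers 1 and 2 (95% exact interval 91.5 to 99.4), 96 in numbers 3 and 4 (90.1 to 98.9) and 93 in numbers 5 and 6 (86.1 to 97.1). These intervals take the probes as independent, though neighbouring probe numbers moved together, so they may be too narrow. They do not measure the spread between samples. The median ratio of the held-out difference to the chosen one was 0.89, 0.86 and 0.61. Over all probes tested, 45.5% had the same direction in the 3 sets of consecutive numbers, where 25% is given by chance.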
